A study of Homo sapiens with 17 samples.

How the data were processed

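RNA editing, in which adenosine in RNA is deaminated to inosine and is then read as guanosine, was measured by RNA sequencing in 17 libraries of HEK293 cells, an established human embryonic kidney line. Of these, 6 were wild type, 4 overexpressed ADAR1, 4 overexpressed ADAR2 and 3 overexpressed AIMP2. Per the labels, the cells were flash frozen and the RNA was extracted with Trizol before sequencing on an Illumina instrument. The authors aligned the reads with STAR 2.4.2a to the hg19 (GRCh37) build. How edited reads were counted, which quality filters were used and where the list of sites came from are not given in the sources used here. Nothing states that the replicates were separate cultures, so the p-values measure the spread between these samples.

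Each deposited file lists the same 2576459 sites with the chromosome, position, gene, strand and annotation (3′ UTR, 5′ UTR, intronic, coding with the amino acid change, ncRNA or intergenic). Per the file headers, coverage and edited reads are in counts of whole reads at each site, with no normalization. The authors give the editing level as a fraction, edited reads divided by coverage, which matched the counts to within 0.0005 at every covered site. Levels are given here in percent of reads, and differences in percentage points. Gene names, positions and annotations were taken from the files as they stand.

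The summed coverage over the listed sites was 9614084 to 16393687 reads in the wild-type libraries, 16038027 to 16582561 with ADAR1, 13693943 to 18699135 with ADAR2 and 9550017 to 11017562 with AIMP2. Between 70685 and 135653 sites per library had at least 20 reads. At 20 reads, 0 edited reads allow a level of up to 16.8% (upper bound of the exact 95% Clopper-Pearson interval), and at 500 reads up to 0.735%. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The mean level at 72 mitochondrial sites, taken as a background of mismatches, was 0.00921% to 0.0311% per library.

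A library entered at a site with at least 20 reads, and a site was tested with at least 3 such libraries in each group and a mean level between 1% and 99%. Edited against unedited reads were compared by a logistic model with a quasi-binomial spread per site. The dispersion was moderated across sites with limma squeezeVar (limma 3.58.1, R 4.3.3) and not allowed below 1, and the deviance was tested with an F-test. P-values were adjusted by Benjamini-Hochberg over the sites of the comparison, with a threshold of 0.05. Tables were handled in R with the data.table package (version 1.17.8) and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. The direction is that of the difference between the group means of the library levels. The 4 comparisons were ADAR1, ADAR2 and AIMP2 overexpression each against wild type, and ADAR2 against ADAR1 overexpression. The mean level per library was taken over 27139 sites with at least 20 reads in all 17 libraries and a mean level in the same range. Groups were compared by exact two-sided permutation of the libraries, adjusted over the 4 comparisons. Classes of sites and gene lists were compared the same way.

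The gene lists were fixed before the data were examined, as were the comparisons, tests and most of the alternatives. There were 8: recoding genes (coding sites only), genes with sites known as ADAR1-preferred, genes with sites known as ADAR2-preferred, transcripts with inverted Alu repeats in the 3′ UTR, genes of double-stranded RNA sensing and interferon, editing enzymes and reported regulators, the aminoacyl-tRNA synthetase complex, and antizyme, DNA repair and p53 genes. A list of 79 interferon-stimulated genes was written after the coverage values had been seen. Sites were named by a fixed rule. It took every tested coding site of the recoding list. It also took the 10 largest rises and the 10 largest falls past the threshold with the libraries of the groups fully apart, at most 2 per gene. From each other list it took the 3 sites with the smallest adjusted p. It named 44, 69, 44 and 71 sites in the 4 comparisons in the order above.

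The library names fall into 3 runs: 12 libraries (wild-type replicates 1 to 4 and all ADAR1 and ADAR2 libraries), 3 (AIMP2 replicates 1 and 2 and wild-type replicate 5) and 2 (wild-type replicate 6 and AIMP2 replicate 3). Clustering of the libraries by their coverage at the 27139 sites named above, cut into 2, split them otherwise. Set 1 held replicates 1 and 2 of wild type, ADAR1 and ADAR2 (6 libraries), and set 2 the other 11. Values within each set are given for the counts, the mean levels and some of the named sites.

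Whether equal replicate numbers pair libraries was checked by correlating site levels, each centred on its group. Pairs with the same number correlated at 0.361 to 0.501 between ADAR1 and wild type, 0.298 to 0.441 between ADAR2 and wild type and 0.361 to 0.459 between ADAR2 and ADAR1. Pairs from the same coverage set with other numbers correlated at 0.0655 to 0.492, 0.0717 to 0.463 and 0.278 to 0.429, so the ranges overlap for levels. Coverage did part numbers 3 and 4. Wild-type replicate 3 correlated at 0.718 and 0.694 with ADAR1 and ADAR2 replicate 3, and at 0.295 and 0.292 with their replicate 4. Wild-type replicate 4 correlated at 0.789 and 0.771 with their replicate 4, and at 0.33 and 0.281 with their replicate 3. Numbers 1 and 2 were not parted by coverage. The main test ignores this pairing. A fit with the replicate number as a block is therefore given beside the ADAR results. Between AIMP2 and wild type, pairs with the same number correlated at only -0.0798 to 0.0483, and the block is given for this comparison among the alternatives only.

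The tests were tried on simulated data with 200 changed sites, at the real coverages. With a binomial spread, 1 to 2 unchanged sites were called (1.45% to 3.57% of calls), 10% to 16% of sites with a 2.01-fold change in odds were recovered, and 44% to 57% of those with a 4.48-fold change. With a spread inflated alike in every library, 5 to 17 unchanged sites were called, and 3% to 6% and 26% to 40% of the changed sites were recovered. With a spread growing with coverage, 6 to 30 were called, and 0% to 7% and 36% to 47% were recovered. The unchanged sites were 11.3% to 41.7% of the calls, above the nominal 5%. The block fit called 12 to 43 unchanged sites under an inflated spread, 30.8% to 51.2% of its calls. A first form of the block fit had called 0 sites in every comparison, because libraries fitted at a level of 0 or 1 counted as degrees of freedom. It was corrected after its calls had been seen.

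The alternatives were other coverage minimums (10, 50, or 20 in every library), no filter on the level, a minimum difference of 5 points, the quasi-likelihood test of edgeR 4.0.16, limma on arcsine levels, Fisher's exact test on summed reads, the spread from all 4 groups, the replicate block, wild-type libraries of the same run only, and leaving out each library in turn. Added after the data had been seen were the coverage set as a factor, each coverage set alone, and a residual degree of freedom that leaves out groups with no edited read. The bases beside each site were not analysed here, because the reference used holds no hg19 genome. Repeat classes were not used here for the same reason.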

Results

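Editing levels were measured at 2576459 listed sites in HEK293 cells, a human embryonic kidney line. The 17 libraries were wild type (n = 6) or overexpressed ADAR1 (n = 4), ADAR2 (n = 4) or AIMP2 (n = 3). ADAR1 and ADAR2 are the enzymes that deaminate adenosine in double-stranded RNA. AIMP2 is a scaffold protein of the aminoacyl-tRNA synthetase complex. Coverage over the listed sites was 9614084 to 16393687 reads per wild-type library, 16038027 to 16582561 with ADAR1, 13693943 to 18699135 with ADAR2 and 9550017 to 11017562 with AIMP2. Levels below are percentages of reads, as mean ± SD over libraries, and positions are on hg19. Coverage at ADAR, ADARB1 (which encodes ADAR2) and AIMP2 itself did not separate the groups with the coverage sets pooled (exact permutation p = 0.143 to 0.881 over the comparisons with wild type, n = 3 to 6). Within the second of the sets described below, AIMP2 coverage was 39.3 to 43.4 CPM (reads scaled to the site coverage of the library) with AIMP2 (n = 3) and 29.3 to 34.7 in wild type (n = 4), a difference that was not tested. In the same set ADAR had 4.523 and 3.429 CPM with ADAR1 and 1.281 to 3.141 in wild type. ADARB1 had 4.76 and 3.87 with ADAR2 and 3.486 to 6.761 in wild type. In the first set ADAR had 5.582 and 3.316 with ADAR1 and 5.2 and 3.563 in wild type. The listed sites of these genes are almost all intronic, so this does not measure the overexpressed transcripts.

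Clustering by coverage at the sites covered in all libraries, cut into 2, divided the libraries into 2 sets, whatever protein was overexpressed. Set 1 held replicates 1 and 2 of wild type, ADAR1 and ADAR2, and set 2 held the other 11 libraries, among them all AIMP2 libraries. Within set 2, coverage of wild-type replicate 4 correlated at 0.789 and 0.771 with that of ADAR1 and ADAR2 replicate 4. With the other libraries of set 2 it correlated at 0.131 to 0.33. Values within set 2 therefore still mix libraries that differ in coverage. Many interferon-stimulated genes had far higher coverage in set 1 than in set 2, and some were nearly absent in set 2. IFIT3, an antiviral protein that interferon induces, had 1940 ± 187 CPM in set 1 (n = 6) and 2.14 ± 2.06 in set 2 (n = 11). MX1, an antiviral GTPase, had 168 ± 17.6 and 0.309 ± 0.575, and DDX58, the RNA sensor RIG-I, had 220 ± 17.2 and 2.92 ± 2.09. The zinc-finger gene ZNF43 had 252 ± 23.8 and 0.29 ± 0.46. Of 9646 genes, 327 had higher coverage in every library of set 1 than in any of set 2 by more than 1 log2 unit, and 112 the reverse. Among 54 covered genes of the interferon list, 41 were higher in set 1 and 0 were higher in set 2. The first principal component of coverage at the sites covered in all libraries, which separated the sets, held 59.1% of the variance.

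**Figure D1:**
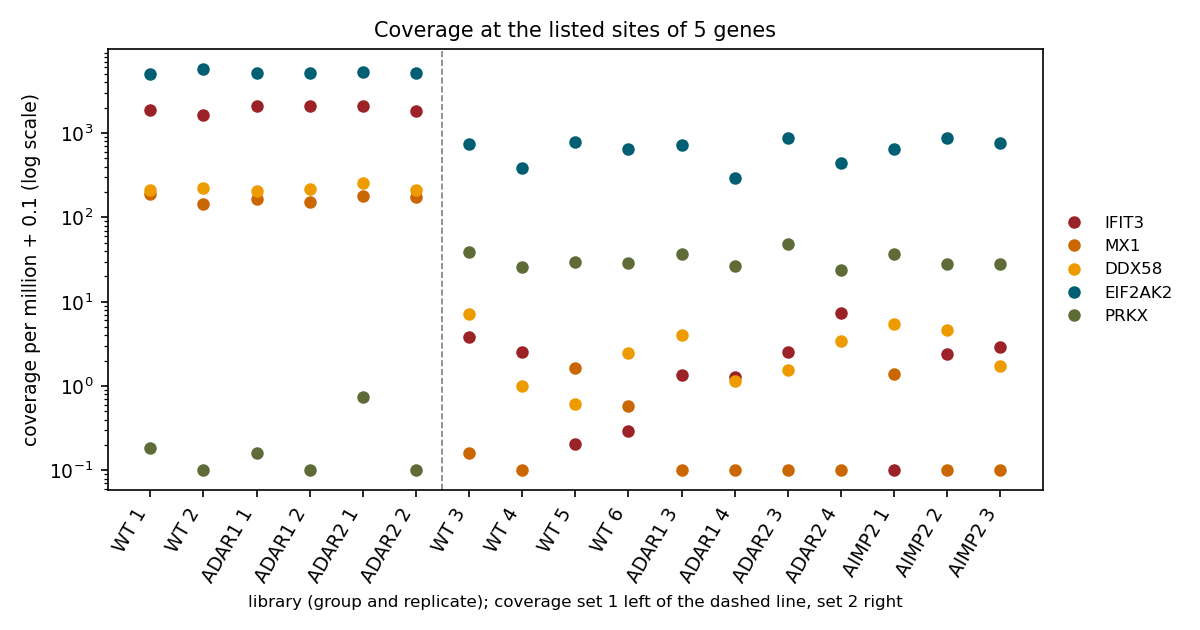
Coverage at the listed sites of 5 genes, in CPM scaled to the site coverage of the library (log scale, 0.1 added), for each of the 17 libraries. IFIT3, MX1, DDX58 and EIF2AK2 lie higher in the 6 libraries left of the dashed line than in the 11 right of it, and PRKX lies lower.

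The first comparison asks which sites ADAR1 edits more when it is overexpressed. A coding site of CCNI, cyclin I, rose with ADAR1 (chromosome 4, 77979680, Arg to Gly). It was edited at 6.45 ± 3.27% with ADAR1 (n = 4) and at 1.26 ± 0.812% in wild type (n = 6), adjusted p = 0.00301. A 3′ UTR site of PAICS, an enzyme of purine synthesis, rose from 0.203 ± 0.116% to 2.27 ± 0.626% (chromosome 4, 57326227, adjusted p = 0.00575). A 3′ UTR site of EIF2S3, a subunit of the translation initiation factor eIF2, rose from 6.62 ± 1.77% to 11.2 ± 1.29% (chromosome X, 24095325, adjusted p = 0.0139). These 3 were the sites past the threshold, of 57281 tested, and 0 were lower. At an unadjusted p under 0.05, 3007 sites were higher and 411 lower.

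Other sites with higher means did not pass. At NCSTN, a subunit of gamma-secretase, a coding site had 7.94 ± 3.96% with ADAR1 (n = 4) and 0.778 ± 0.904% in wild type (chromosome 1, 160319987, Ser to Gly, adjusted p = 0.128). Among 3′ UTR sites, XIAP, an inhibitor of caspases, had 3.4 ± 1.19% and 0% (chromosome X, 123046629, adjusted p = 0.147), and EIF2AK2, the kinase PKR, had 3.29 ± 2.89% and 0.13 ± 0.251% (chromosome 2, 37328132, adjusted p = 0.0782). With the replicate block all of these passed, at adjusted p = 2.13e-06 for NCSTN, 0.00873 for XIAP and 1.81e-05 for EIF2AK2. The block fit had been corrected after its calls had been seen. In simulated data with an inflated spread, 43.2% and 48.1% of its calls for this comparison were unchanged sites. AZIN1, the antizyme inhibitor, had 5.8 ± 2.57% and 2.26 ± 2.29% at its Ser to Gly site (chromosome 8, 103841636, adjusted p = 0.802). NEIL1, a DNA glycosylase, had a lower mean at its Lys to Arg site, 66.3 ± 4.35% against 79.1 ± 7.08% (chromosome 15, 75646086, adjusted p = 0.802). Both differences had the same direction in each coverage set. AZIN1 had 7.32% with ADAR1 and 4.38% in wild type in set 1, and 4.28% and 1.2% in set 2. NEIL1 had 62.7% and 74.7% in set 1, and 70% and 81.3% in set 2.

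By list, CCNI was the 1 site past the threshold of 28 in recoding genes. Adjusted over the list alone, 3 were higher and 1 was lower. In genes with sites known as ADAR1-preferred, 0 of 1012 passed, and 1 was higher adjusted over the list alone. In 3′ UTR inverted Alu transcripts, 0 of 2138 passed, with 2 higher adjusted over the list alone, and in double-stranded RNA sensing and interferon genes, 0 of 640, with 1. None of 8 sites in ADAR2-preferred genes, 19 in editing enzymes, 17 in the synthetase complex or 407 in antizyme, DNA repair and p53 genes passed under the limma-moderated test, over all sites or adjusted over the list alone. The mean level over the common sites was 11.7 ± 0.335% with ADAR1 (n = 4) and 10.3 ± 1.29% in wild type (n = 6). The difference of 1.35 points did not pass the exact permutation test (p = 0.0905, adjusted p = 0.121). Without wild-type replicate 6 it was 1.68 points and passed (exact permutation p = 0.0238, adjusted p = 0.0476). With the block it was 1.23 points, positive in 4 of 4 pairs (exact p = 0.125, the smallest that 4 pairs allow). It was 0.555 points within set 1 and 1.86 within set 2.

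The 3 sites are no more than the 5 to 30 unchanged sites called in simulated data with an inflated spread. Those data held 200 changed sites, whose recovery loosens the adjusted threshold, so how many of the 3 are false was not measured. The count was 0 without ADAR1 replicate 3 or 4, where the PAICS site was no longer among those tested. It was 7 without wild-type replicate 1 and 14 without wild-type replicate 2. With the block 74 sites were higher, and within coverage sets 0 passed in set 1 (3132 at an unadjusted p under 0.05) and 97 in set 2. At CCNI the means with ADAR1 and in wild type were 3.67% and 0.688% in set 1 (n = 2 and 2), and 9.24% and 1.55% in set 2 (n = 2 and 4). At NCSTN they were 4.51% and 1.65% in set 1, and 11.4% and 0.34% in set 2. The call at CCNI ended without ADAR1 replicate 3 or 4, and that at EIF2S3 without ADAR1 replicate 1, 3 or 4 or wild-type replicate 3 or 4. The EIF2S3 site did not pass either at a coverage minimum of 50 or of 20 in every library, with no filter on the level, by edgeR or with the spread from all 4 groups. On the same sites, edgeR called 5 and limma on arcsine levels 0 (2889 at an unadjusted p under 0.05).

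**Figure D2:**
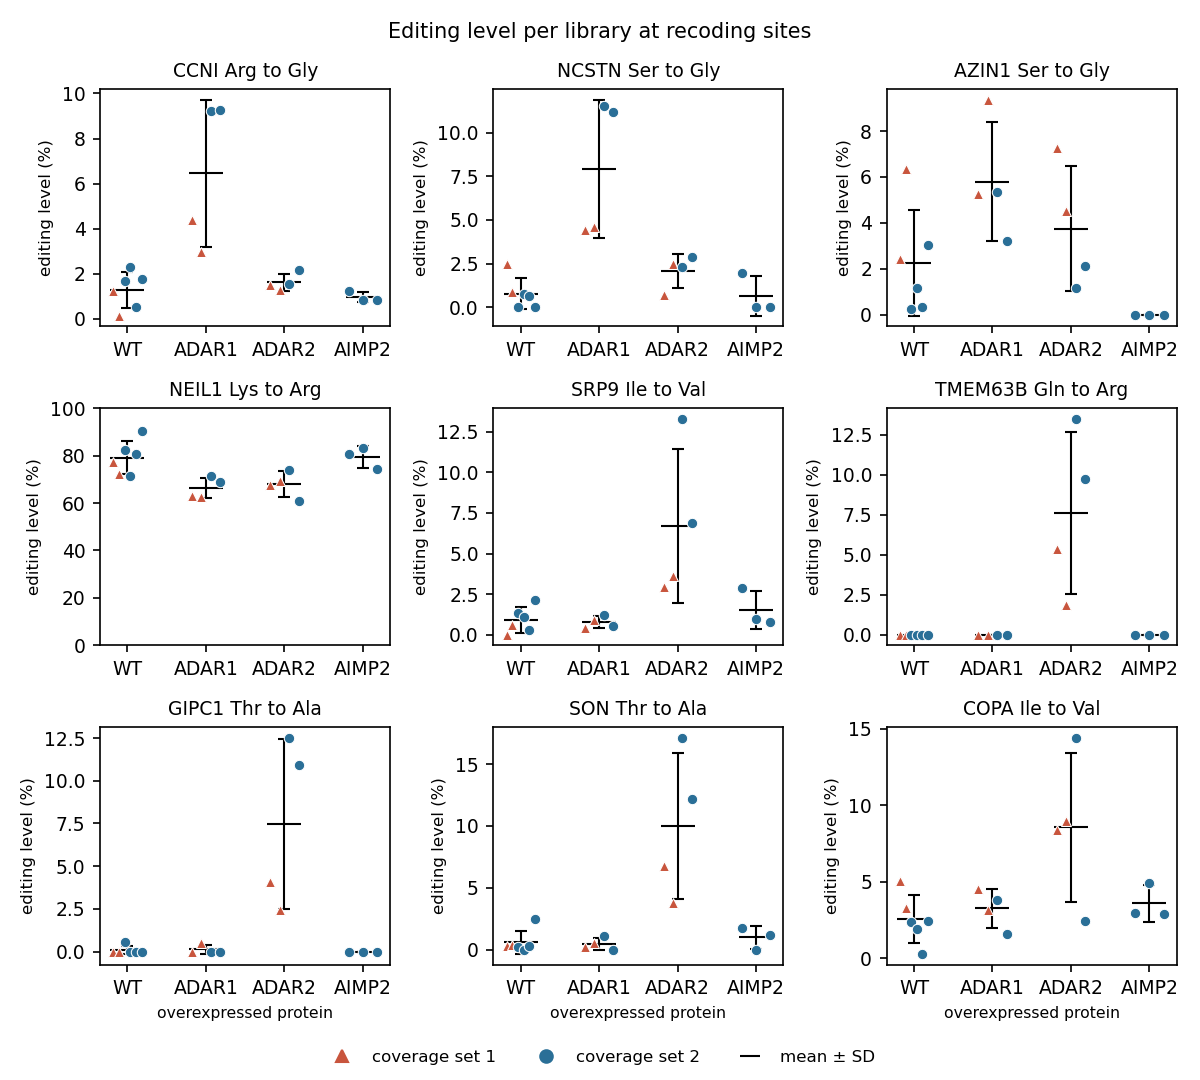
Editing level (percent of reads) at 9 coding sites, 1 point per library, in wild type (WT) and with ADAR1, ADAR2 or AIMP2 overexpressed. Black bars give the mean ± SD of the group and the shape gives the coverage set. CCNI reaches 6.45% on average with ADAR1 and TMEM63B 7.61% with ADAR2.

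The second comparison asks the same of ADAR2, and here editing rose at many sites. FLNA, an actin-binding filamin, rose from 0% (n = 5) to 20.5 ± 6.01% (n = 4) at an intronic site (chromosome X, 153579737, adjusted p = 4.97e-05). TMEM63B, a membrane cation channel, rose from 0% in all 6 wild-type libraries to 7.61 ± 5.09% at a coding site (chromosome 6, 44120349, Gln to Arg, adjusted p = 0.000223). Of 62315 sites tested, 3951 in 771 genes were higher and 20 were lower. The median level of those that rose was 1.49% in wild type and 11% with ADAR2.

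Of 34 sites in recoding genes, 9 rose and 0 fell. Adjusted over the list alone, 11 were higher and 1 was lower. Those that rose included SON, a splicing cofactor, from 0.613 ± 0.93% to 9.99 ± 5.91% (chromosome 21, 34922801, Thr to Ala, adjusted p = 0.000267). COPA, a coat protein of Golgi vesicles, rose from 2.56 ± 1.58% to 8.55 ± 4.89% (chromosome 1, 160302244, Ile to Val, adjusted p = 0.00124). GIPC1, a PDZ-domain adaptor, rose from 0.0896 ± 0.219% to 7.47 ± 4.96% (chromosome 19, 14593605, Thr to Ala, adjusted p = 0.000878). SRP9, a subunit of the signal recognition particle, rose at 3 of its tested sites, among them Ile to Val from 0.899 ± 0.79% to 6.68 ± 4.74% (chromosome 1, 225974612, adjusted p = 0.000896). Among sites that did not pass were 2 already edited to a high level. NEIL1 had 67.8 ± 5.52% at its Lys to Arg site with ADAR2 and 79.1 ± 7.08% in wild type (adjusted p = 0.116), and CDK13, a transcription kinase, had 76 ± 2.33% (n = 3) and 75.9 ± 3.83% (n = 5) at a Gln to Arg site (chromosome 7, 39990548, adjusted p = 0.999). AZIN1 had 3.76 ± 2.72% and 2.26 ± 2.29% (adjusted p = 0.563).

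In genes with sites known as ADAR2-preferred, 8 of 16 sites rose, and 11 adjusted over the list alone. In genes with sites known as ADAR1-preferred, 108 of 1102 rose, with 140 higher and 1 lower adjusted over the list alone. In 3′ UTR inverted Alu transcripts, 338 of 2301 rose, and 463 adjusted over the list alone. EIF2AK2, MDM2, MDM4 and MAVS are on this list and on other lists, so some sites count in more than 1 list. BPNT1, a nucleotidase, rose from 0.19 ± 0.295% to 11.6 ± 5.23% (chromosome 1, 220231492, adjusted p = 4.25e-06). DFFA, the inhibitor of a DNase of apoptosis, rose from 6.81 ± 2.01% to 22 ± 4.76% (chromosome 1, 10517998, adjusted p = 7.97e-06), and 70 of its 342 sites rose. In double-stranded RNA sensing and interferon genes, 64 of 706 rose (37 of them in EIF2AK2), and 80 adjusted over the list alone. Of these, EIF2AK2 rose from 2.8 ± 1.81% to 25.3 ± 10.7% (chromosome 2, 37327644, adjusted p = 6.8e-06). In antizyme, DNA repair and p53 genes, 78 of 465 rose (51 of them in MDM4), with 125 higher and 3 lower adjusted over the list alone. The p53 regulators MDM4 and MDM2 were among them, MDM4 from 0% to 6.63 ± 4.7% (chromosome 1, 204525795, adjusted p = 0.0002) and MDM2 from 5.03 ± 3.27% to 20.5 ± 7.9% (chromosome 12, 69237024, adjusted p = 0.000295). Of editing enzymes and regulators, 2 of 20 rose, with 3 higher and 1 lower adjusted over the list alone. Of the synthetase complex, 2 of 27 rose, and 2 adjusted over the list alone. These were in LARS, from 0% to 2.89 ± 1.94% in the 3′ UTR (chromosome 5, 145492739, adjusted p = 0.00281), and in IARS, from 0% to 8.17 ± 11.4% in an intron (chromosome 9, 95017225, adjusted p = 0.0101). LARS and IARS encode the leucyl- and isoleucyl-tRNA synthetases. The IARS rise came from set 2 alone, since both ADAR2 libraries of set 1 were at 0%, and without ADAR2 replicate 3 the site was not tested.

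Large rises also lay in introns and 3′ UTRs. TRAP1, a mitochondrial chaperone, rose from 10.2 ± 3.75% (n = 5) to 44.6 ± 11.5% (n = 4) at an intronic site (chromosome 16, 3728570, adjusted p = 0.0006), and 25 of its 48 sites rose. NICN1, nicolin, rose from 4.72 ± 3.99% (n = 4) to 37.8 ± 7.84% (n = 4) in its 3′ UTR (chromosome 3, 49460998, adjusted p = 0.00179). Of the sites that fell, PEX26, a peroxisome biogenesis factor, went from 26.1 ± 3.42% to 13.5 ± 3.5% in its 3′ UTR (chromosome 22, 18571338, adjusted p = 0.00469). By annotation, 2061 of 27031 sites in 3′ UTRs rose (7.62%), 1000 of 19115 in introns (5.23%), 24 of 313 nonsynonymous sites (7.67%) and 501 of 11567 intergenic sites (4.33%). The shares were highest in 5′ UTRs (68 of 715, 9.51%), at synonymous sites (13 of 144, 9.03%) and in ncRNA (284 of 3430, 8.28%).

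**Figure D3:**
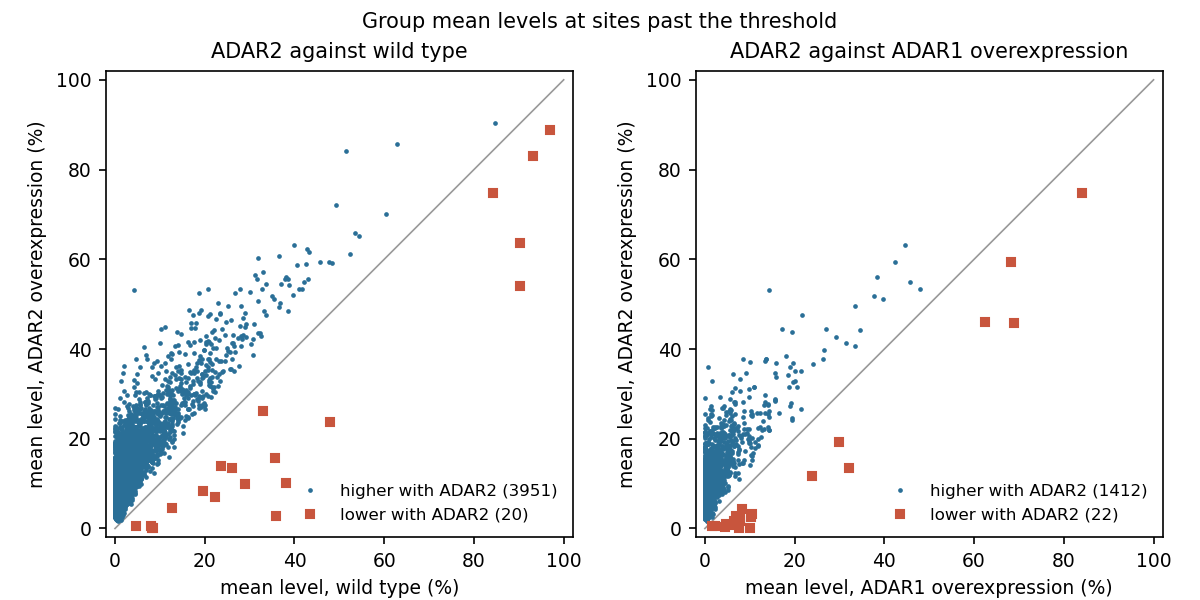
Mean editing level (percent of reads) with ADAR2 overexpressed against wild type (left) and against ADAR1 overexpression (right), 1 point per site past the threshold, with the line of equal levels. Against wild type 3951 sites lie above the line and 20 below, and against ADAR1 overexpression 1412 and 22.

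The mean level over the common sites was 12.9 ± 0.908% with ADAR2 (n = 4) and 10.3 ± 1.29% in wild type (n = 6), a difference of 2.57 points (exact permutation p = 0.00952, adjusted p = 0.0381). The adjusted call was kept without ADAR2 replicate 2 or wild-type replicate 6 (adjusted p = 0.0476 each). It was lost without any other library of these groups (adjusted p = 0.0635 to 0.121, exact permutation tests). Fewer libraries leave fewer splits, so the smallest possible p rises. Without 1 library the difference stayed at 2.14 to 2.9 points (unadjusted exact permutation p = 0.0119 to 0.0476). The lowest ADAR2 library (11.96%) lay just above the highest wild-type library (11.95%). With the block the difference was 2.45 points, positive in 4 of 4 pairs (exact p = 0.125, the smallest that 4 pairs allow), and it was 1.39 points within set 1 and 3.46 within set 2. None of the class or list means passed in any comparison (smallest adjusted p = 0.133 for classes and 0.0762 for lists, exact permutation tests). The count was 6041 with the block, 60 within set 1, 4567 within set 2 and 1379 by limma on arcsine levels. It was 1214 without ADAR2 replicate 3, 2519 without wild-type replicate 3 and 2606 without wild-type replicate 4. Within set 1 alone, TMEM63B, GIPC1, COPA, LARS, DFFA, BPNT1, TRAP1, PEX26, the SRP9 Ile to Val site and the MDM4 site did not pass. PEX26 did not pass within set 2 alone either. The set 1 means still differed in the pooled direction, for example 3.6% against 0% at TMEM63B (n = 2 and 2).

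**Figure D4:**
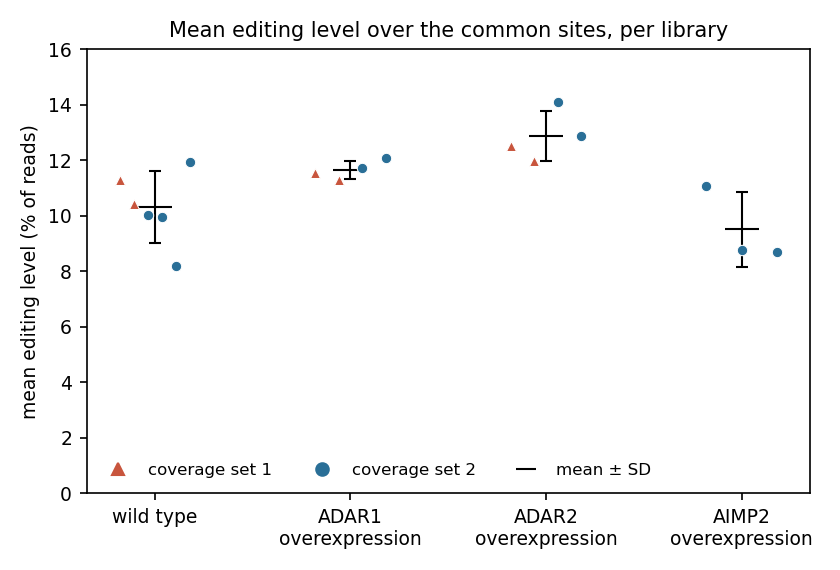
Mean editing level over the 27139 common sites (percent of reads), 1 point per library, by group. Black bars give the mean ± SD and the shape gives the coverage set. Wild-type libraries range from 8.19% to 12% and ADAR2 libraries from 12% to 14.1%.

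The third comparison asks whether AIMP2 overexpression changes editing. Levels were lower on average with AIMP2 than in all wild-type libraries pooled, but no site passed the test. F11R, a junctional adhesion molecule, had 69 ± 6.91% with AIMP2 (n = 3) and 85.1 ± 1.95% in wild type (n = 6) at a 3′ UTR site (chromosome 1, 160966434). PSMB2, a proteasome subunit, had 47.6 ± 6.77% and 63.9 ± 9.35% (chromosome 1, 36068184, 3′ UTR), and MDM2 had 3.55 ± 1.88% and 10.9 ± 5.74% (chromosome 12, 69237021, 3′ UTR). IFNAR1, a subunit of the type I interferon receptor, had 9.5 ± 5.02% and 22.3 ± 10.1% (n = 5) in its 3′ UTR (chromosome 21, 34730108). AZIN1 had 0% in all 3 AIMP2 libraries and 2.26 ± 2.29% in wild type at its Ser to Gly site. The adjusted p was 0.856 at each of these, the smallest in the comparison. All AIMP2 libraries are of set 2, and against wild type of set 2 alone the differences were -16.5 points at F11R, -11 at PSMB2, -4.24 at MDM2 and -6.93 at IFNAR1, in place of -16.1, -16.3, -7.35 and -12.8. AZIN1 had 1.2% in wild type of set 2 and 4.38% in that of set 1. NEIL1 had 79.3 ± 4.7% and 79.1 ± 7.08% at its Lys to Arg site (adjusted p = 0.98).

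Of 35152 sites tested, 59.9% had a lower mean with AIMP2, with a median difference of -0.618 points. The limma-moderated test called 0 sites, with 451 higher and 1571 lower at an unadjusted p under 0.05. On the same sites edgeR and limma on arcsine levels also called 0 (1760 and 1915 at an unadjusted p under 0.05), and Fisher's exact test on summed reads, which takes no account of the spread between libraries, called 560, of which 501 were lower. None of the sites in the lists passed, over all sites or adjusted over the list alone: 0 of 28 in recoding genes, 868 in ADAR1-preferred genes, 7 in ADAR2-preferred genes, 1827 in 3′ UTR inverted Alu transcripts, 448 in double-stranded RNA sensing and interferon genes, 7 in editing enzymes, 4 in the synthetase complex and 348 in antizyme, DNA repair and p53 genes. The mean level was 9.52 ± 1.35% with AIMP2 (n = 3) and 10.3 ± 1.29% in wild type (n = 6). The difference of -0.787 points was smaller than the spread within either group (exact permutation p = 0.417, adjusted p = 0.417). Leaving out 1 library moved it to between -1.57 and -0.382 points (exact permutation p = 0.161 to 0.786). Within set 2, which holds all AIMP2 libraries and 4 of the wild-type libraries, it was -0.514 points, and 0 sites passed there (1603 at an unadjusted p under 0.05). Within the library-name runs the direction was not the same. In the run of AIMP2 replicates 1 and 2 (11.1% and 8.77%), wild-type replicate 5 had 8.19%, lower than both. In the run of AIMP2 replicate 3 (8.71%), wild-type replicate 6 had 11.95%, which was higher. These differences within a run were not tested.

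The fourth comparison sets ADAR2 against ADAR1 overexpression. The enzymes differed in opposite directions at recoding sites. With ADAR2, CCNI was lower at the Arg to Gly site (1.62 ± 0.38% against 6.45 ± 3.27%, n = 4 and 4, adjusted p = 0.000549) and NCSTN was lower at the Ser to Gly site (2.08 ± 0.967% against 7.94 ± 3.96%, adjusted p = 0.0329). TMEM63B was higher with ADAR2 (7.61 ± 5.09% against 0%, adjusted p = 0.00127), as were SON at the Thr to Ala site (9.99 ± 5.91% against 0.485 ± 0.473%, adjusted p = 0.000703) and GIPC1 at the Thr to Ala site (7.47 ± 4.96% against 0.124 ± 0.249%, adjusted p = 0.00657). The FLNA intronic site had 20.5 ± 6.01% against 0% (adjusted p = 0.000208). AZIN1 had 3.76 ± 2.72% with ADAR2 and 5.8 ± 2.57% with ADAR1 (adjusted p = 0.422). A second coding site of CCNI, Lys to Arg, had 0.511 ± 0.756% and 2.17 ± 1.67% (chromosome 4, 77977164, adjusted p = 0.0653), and passed with the block (adjusted p = 1.07e-07). In simulated data with an inflated spread, 34.4% and 50% of the block calls for this comparison were unchanged sites.

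Of 62810 sites tested, 1412 in 430 genes were higher with ADAR2 and 22 were lower. Of those higher, 48.8% had a mean under 1% with ADAR1. In recoding genes 8 of 35 sites were higher and 2 lower, or 9 and 3 adjusted over the list alone. In ADAR2-preferred genes 6 of 16 were higher, or 10 adjusted over the list alone, and in ADAR1-preferred genes 40 of 1143, or 63. In 3′ UTR inverted Alu transcripts 129 of 2397 were higher and 1 lower, or 201 and 4 adjusted over the list alone. In double-stranded RNA sensing and interferon genes 30 of 739 were higher and 1 lower, or 57 and 2 adjusted over the list alone, among them EIF2AK2 (11.9 ± 5.63% against 1.5 ± 1.44%, chromosome 2, 37328076, adjusted p = 0.000275). In antizyme, DNA repair and p53 genes 30 of 484 were higher, or 58 adjusted over the list alone, among them MDM4 (16.8 ± 10.6% against 1.97 ± 1.45%, chromosome 1, 204525629, adjusted p = 0.000458). In the synthetase complex 1 of 34, the IARS site, was higher, both ways, and in editing enzymes 0 of 20, both ways. A large difference lay in SPG7, a mitochondrial protease, at 36 ± 9.77% against 0.735 ± 1.47% (chromosome 16, 89615997, intronic, adjusted p = 0.00145). PEX26 was lower with ADAR2 (13.5 ± 3.5% against 32.2 ± 10.9%, adjusted p = 0.0183), as was ARL10, a small GTPase (0.192 ± 0.385% against 7.52 ± 0.986%, chromosome 5, 175803213, 3′ UTR, adjusted p = 0.0232).

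The mean level was 12.9 ± 0.908% with ADAR2 and 11.7 ± 0.335% with ADAR1 (n = 4 and 4). The difference of 1.22 points did not pass (exact permutation p = 0.0571, adjusted p = 0.114). It was 1.22 with the block (exact p = 0.125), 0.838 within set 1 and 1.6 within set 2. The count of 1434 sites was 4006 with the block, 13 within set 1, 1247 within set 2 and 12 by limma on arcsine levels. It was 362 without ADAR2 replicate 3, and 721, 709, 530 and 767 without ADAR1 replicates 1 to 4. The call at NCSTN ended without ADAR2 replicate 1 or 3 or ADAR1 replicate 3 or 4, that at PEX26 without ADAR2 replicate 3 or ADAR1 replicate 3, that at IARS without ADAR2 replicate 3 or 4 or any 1 ADAR1 library, and that at ARL10 without ADAR2 replicate 3 or 4 or ADAR1 replicate 1, 3 or 4.

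The last comparison asks whether the proteins act on the same sites. The EIF2S3 site that rose with ADAR1 also rose with ADAR2, to 17.8 ± 4.4% (n = 4). It was the 1 site called higher in both comparisons with wild type among 52068 tested in both, and its call with ADAR1 was lost under 13 of the 25 alternatives. Sharing the wild-type libraries alone gave 0 such sites in 20 simulations. At an unadjusted p under 0.05, 1335 sites were higher with both enzymes, against 450 if the comparisons were independent and 4.3 in the simulations. The simulated groups held no changed sites, so 0 is not a reference for the 1 shared site, nor 4.3 for 1335. The differences of the enzymes from wild type correlated at 0.442 across these sites, against 0.163 in the simulations, and sites are not independent replicates. Set 1 makes up a larger share of the libraries of each enzyme than of wild type. A difference between the sets therefore enters both comparisons alike and can raise the correlation and the count of 1335. How much of either comes from this was not tested. With separate wild-type libraries for each enzyme, drawn 20 times, the correlation averaged 0.0731 and the count of shared sites at an unadjusted p under 0.05 averaged 374, against 290 if independent. Between AIMP2 and ADAR1 the correlation was 0.0588 (0.117 in the simulations), between AIMP2 and ADAR2 it was 0.0673 (0.121 in the simulations), and 0 sites were called in both. With separate wild-type libraries these correlations averaged -0.273 and -0.198. The separate libraries were the same 6 wild-type libraries, split into 3 and 3. A draw with more set 1 libraries on 1 side had fewer on the other, which can by itself lower the correlation. The correlations with separate libraries and the count of 374 therefore do not measure how far the proteins share sites.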

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

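The sites below were looked at because the level in 1 library lay far from the others of its group. Of 368 groups of libraries examined, 27 had such a library (7.34%), and all were at named sites. The rule flags about 1 in 20 groups of normally distributed values, which levels near 0% are not, so no comparison with chance is made. Wild-type replicate 6 and ADAR2 replicate 3 gave 5 each, and in 10 the other libraries were all at 0%, where any edited read is flagged. No explanation was weighed for single sites. Intervals are exact 95% intervals and cover counting error only.

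In the wild-type libraries, replicate 6 had 5.41% (0.661 to 18.2) at CDK13 on chromosome 7, 39990299, others 0% to 1.18%, and 25% (12.7 to 41.2) at CDK13 39990344, others 3.03% to 9.38%. At SON on chromosome 21 it had 13.4% (9.49 to 18.3) at 34923319, others 2.47% to 6.25%, and 2.49% (0.919 to 5.34) at 34922801, others up to 0.429%. At RARS, 167922904, it had 3.45% (0.0873 to 17.8), others 0%. Replicate 4 had 3.34% (2.25 to 4.77) at SRP9 225974662, others 0.768% to 1.71%, and levels above others at 0% at NPM1 170836404 (1.32%, 0.0333 to 7.11), EIF2AK2 37329296 (6.25%, 0.766 to 20.8) and MDM4 204521598 (2.2%, 0.267 to 7.71). Replicate 5 was lower at PGAM5 133297904, with 49.8% (43.7 to 56) against 60.1% to 65.8%, and at NPM1 170836398, with 7.69% (0.946 to 25.1) against 22.2% to 23.8%. Replicate 1 had 2.46% (0.997 to 5.01) at NCSTN 160319987, others up to 0.843%. Replicate 2 had 0.626% (0.23 to 1.36) at EIF2AK2 37328132, others up to 0.155%. Replicate 3 had 0.538% (0.0136 to 2.96) at GIPC1 14593605, others 0%.

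With ADAR1, replicate 3 had 4.17% (0.868 to 11.7) at CDK13 39990299 and 3.28% (0.4 to 11.3) at CDK13 39990623, and replicate 2 had 0.498% (0.0126 to 2.74) at GIPC1 14593605 and 2.94% (0.0744 to 15.3) at SPG7 89615997, with the other libraries at 0% at each. Replicate 4 had 16.7% (4.74 to 37.4) at CDK13 39990590, others 4.76% to 6.19%, and 4.79% (3.38 to 6.57) at SRP9 225974644, others 3.37% to 3.48%. It had 3.64% (0.443 to 12.5) at EIF2AK2 37328076, others 0.491% to 1.01%, and was lower at F11R 160966434, with 68.4% (59.8 to 76.2) against 83.8% to 86.4%.

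With ADAR2, replicate 3 was higher at every site found in this group. It had 8.33% (4.63 to 13.6) at BLCAP on chromosome 20, 36147533, others 3.8% to 4.26%, 15.9% (13.6 to 18.5) at SRP9 225974662, others 5.99% to 6.99%, and 24.4% (22.3 to 26.6) at EIF2S3 24095325, others 15.1% to 16%. At EIF2AK2 37327644 it had 41.2% (30.4 to 52.8), others 18.8% to 21%, and at ARL10 175803213 0.769% (0.0195 to 4.21), others 0%. Without this library 1214 sites in place of 3971 were called against wild type.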

How the results depend on the processing

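The coverage set as a factor, each coverage set alone and the degrees of freedom without groups that have no edited read were chosen after seeing the data. The other alternatives were planned. Except where a sentence says otherwise, the cause of a change was not tested.

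For ADAR1 against wild type, 3 sites were called, against 8 at a coverage minimum of 10, 1 with a difference of at least 5 points, 5 by edgeR, 0 by limma on arcsine levels, 948 by Fisher's exact test on summed reads, 8 with the other degrees of freedom, 140 with the coverage set as a factor, 0 in set 1 alone and 97 in set 2 alone. Leaving out 1 library gave 0 to 14. For ADAR2 against wild type, 3971 became 1995 at a minimum of 50, where fewer sites were tested, 1379 by limma, 10950 by Fisher's test, 2589 with the wild-type libraries of the same run, 7879 with the set as a factor and 60 in set 1 alone, and 1214 to 4230 without 1 library. For AIMP2, 0 became 560 by Fisher's test, which by construction leaves out the spread between libraries, and stayed 0 without any 1 library. For ADAR2 against ADAR1, 1434 became 740 at a minimum of 50, 12 by limma, 5890 by Fisher's test, 2256 with the spread from all 4 groups, 4403 with the set as a factor and 13 in set 1 alone, and 362 to 1796 without 1 library.

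With the replicate block, in the form corrected after its calls had been seen, the counts were 74, 6041, 507 and 4006 in the same order. For AIMP2, 481 of the 507 were lower. The replicate numbers of AIMP2 and wild type did not pair by level, and the block fit called too many unchanged sites in simulated data. The block left the mean difference of ADAR2 from wild type at 2.45 points, with the smallest p-value that 4 pairs allow above 0.05.

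The mean difference of ADAR1 from wild type was 1.52 points at a minimum of 50 (exact permutation p = 0.0476, adjusted p = 0.0635) and 0.924 to 1.68 without 1 library. That of ADAR2 was 1.39 in set 1 alone and 3.46 in set 2 alone, where fewer libraries cannot reach 0.05, and 2.14 to 2.9 without 1 library. Its adjusted p, 0.0381, was 0.0476 to 0.121 without 1 library, above 0.05 in 8 of 10 cases, and also failed at a minimum of 10 (0.0952) or 50 (0.0571) and with wild type of the same run (0.0762, all exact permutation tests). That of AIMP2 was -1.57 to -0.382 without 1 library. That of ADAR2 from ADAR1 was 1.02 at a minimum of 50 and 1.17 as edited reads over all reads (both exact permutation p = 0.0286, adjusted p = 0.0571), and 0.807 to 1.52 without 1 library. The 1 site called with both ADAR1 and ADAR2 became 0 at 5 points and 5 on average with separate wild-type libraries for each enzyme, and 0 for ADAR2 and AIMP2 became 0.1 with separate ones.

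None of these values changed direction. The single library-name runs, where the AIMP2 difference did not keep its direction, were not among the alternatives. Under the alternatives chosen beforehand the named sites kept their direction and side of the threshold 3993 times, gained the call 92 times and lost it 201 times, and under the added ones 648, 41 and 76 times. The counts per list stayed within 1.5 times 320 times, moved 42 times, gained a call 6 times and lost all calls 16 times. The means per class and per list stayed on their side of the threshold all 336 times each. The bases beside each site were not analysed here. At 20 reads a level under 16.8% can give 0 edited reads, so small changes at thinly covered sites go unseen.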

Other observations

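The tests of interferon genes, zinc-finger genes and the mismatch background were chosen only after the result was seen. The tests of another person's line, of an exchange of libraries and of other splits were planned.

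The coverage sets described above were weighed as a pattern: of the genes covered in 1 set and near 0 in the other, 60% were not on the interferon list. These were 7 of 13 genes covered in set 1 and 2 of 2 covered in set 2. Some of the 7 are unnamed transcripts, which a list of gene symbols cannot hold, and the list was written after the coverage had been seen. The share therefore argues only weakly against an interferon response as the only difference. A line from another person in 1 set remains open: 0 sites (0%) lay at 90% or more in every library of 1 set and at 2% or less in the other, against 32 sites at 90% or more in all 17 libraries, and 0 lay at 30% or more in 1 set and at 2% or less in the other, against 2397 at 30% or more in all, which goes against it, but the sites are those of an editing list, and whether variants were removed from that list is not given. Of 286 genes higher in set 1 and not on the interferon list, 55 (19.2%) were zinc-finger genes, against 2.61% of the other genes (odds ratio 8.87, 95% interval 6.32 to 12.3). Loss of promoter methylation, or another stock of the line with less of it, may therefore be a candidate explanation. No methylation was measured, and no biological explanation from the design was tested, since both sets hold wild type, ADAR1 and ADAR2.

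The mean levels of the 5 libraries of the later runs spread over 3.76 points, from 8.19% in wild-type replicate 5 to 12% in wild-type replicate 6, more than AIMP2 and wild type differed. The mitochondrial levels of these libraries ranged over only 0.0219 points, which argues against a mismatch background. An exchange of AIMP2 replicate 1 (11.1%) and wild-type replicate 5 stays open: on a coverage score from wild type (0) to AIMP2 (1) they had 0.29 and 0.506, as an exchange needs, but wild-type replicates 3, 4 and 6 had 0.609, 0.34 and 0.607 and AIMP2 replicates 2 and 3 had 0.606 and 0.643, so the score does not separate the groups, and coverage of AIMP2 itself ran as labelled (40.2 CPM in AIMP2 replicate 1, 39.3 and 43.4 in replicates 2 and 3, 34.7 in wild-type replicate 5 and 29.3 to 33.6 in the other set 2 wild type), though almost all at intronic sites. The centred site levels, in which the pattern was seen, are no separate test: wild-type replicate 5 correlated at 0.271 and 0.292 with AIMP2 replicates 2 and 3, at -0.0137 with wild-type replicate 6 and at 0.223 and 0.143 with wild-type replicates 3 and 4, and AIMP2 replicate 1 at 0.297 with wild-type replicate 6 and at 0.132 and 0.128 with AIMP2 replicates 2 and 3. An effect of AIMP2 stays untested apart from these.

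Other splits of the same libraries into groups of the same sizes were tested. For ADAR2 against wild type, 1 of 100 splits, the real one, gave as many as 3971 sites. The highest other gave 1528, and 84 gave 0. The share is under 0.05 for splits that ignore the pairs and the sets. Libraries of different sets are not interchangeable, so the share does not exclude chance where pairs and sets are kept. For ADAR1 against wild type, 10 of 100 gave at least 3, so chance cannot be excluded. The highest other gave 1774, with ADAR1 replicate 3 and wild-type replicates 3, 4 and 5, all of set 2, as a group, which points to the structure of the sets. The counts within sets were 0 in set 1 and 97 in set 2. For AIMP2 the real count was 0, so all 84 splits gave at least as many whatever the data, which says nothing about chance. The highest other gave 1721, with wild-type replicates 1 and 2, the libraries of set 1, in the same group. Within set 2 the real count was 0. For ADAR2 against ADAR1, 2 of 35 gave as many as 1434 (5.71%), and the other, at 3272, was the split along the coverage sets. Chance cannot be excluded there at the 0.05 level. The blocked count was 4006, with 13 in set 1 and 1247 in set 2.

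Where the replicate numbers pair the libraries, splits that part every pair are the closer reference. For ADAR1 against wild type the highest of the 15 others gave 0 sites, and with the block 38 against the real 74. For ADAR2 against wild type the highest other without the block gave 426, in the split that exchanges the groups in every pair, and the next gave 308. With the block the highest other gave 934 against 6041. For ADAR2 against ADAR1 they gave 0, and with the block 674 against 4006. With the block, the split that exchanges the groups in every pair tests the same differences with the sign turned. It called 89 sites for ADAR1, more than the real 74, and 6031 for ADAR2. It was left out of the highest others with the block only, after its counts had been seen. There are 16 such splits against wild type and 8 between the enzymes, and 8 distinct ones with the block, too few for a share under 0.05.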
